A study of Mus musculus with 9 samples.

How the data were processed

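Poly(A) RNA was sequenced from 9 libraries of D2.0R (also written D2.OR), a mouse mammary gland adenocarcinoma cell line. Per the labels' protocols, the cells were loaded with CellTrace Far Red, a dye that is diluted at each division, kept for a week in medium with 2% serum, and sorted by flow cytometry into dye-retaining and dye-poor cells. RNA was isolated with a Qiagen RNeasy kit and the libraries were made by a university genomics core.

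The labels do not say which library is which. All 9 samples carry 1 identical description, which names 3 kinds of sample (CTFR-positive, bulk and CTFR-negative) with the numbers 1 to 3 each, and the titles differ only in a running number from 1 to 9. Matching the list to the titles would rest on their order alone, so 0 of the 9 libraries were given a group and no comparison between sorted fractions was made. Libraries are named here by their title number, and values are given library by library, with ranges and medians but without a mean and SD, since libraries of unknown kind are not replicates of one another. Whether any of them came from separate cultures is not given in the sources used here.

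The authors deposited 1 table of estimated counts per gene (RSEM expected counts, already rounded to whole numbers and not normalised) with 55492 rows, of which 5 are reporter or Cre sequences with no counts in any library. The submitters' processing notes name cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3 and the mouse genome build GRCm38. The annotation release and whether strand was used are not given in the sources used here. RSEM divides reads that fit several genes between them by likelihood, so values of near-identical genes (MHC class I, the Raet1 family, histones, ferritin and mitochondrial genes with nuclear copies) are less certain than those of single-copy genes, and a gene cannot be told from an overlapping antisense partner unless strand was used. Every one of the 9 count columns matched 1 sample title, and 0 columns were left unmapped.

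The totals ran from 18732737 estimated counts in library 9 to 41243036 in library 7. One CPM therefore rested on about 19 to 41 counts, and a count of 3, the floor used here, corresponded to between 0.0742 CPM in library 7 and 0.164 CPM in library 9. Intervals are exact 95% intervals (Poisson for a value, conditional binomial for a ratio of libraries). They cover counting error only, and PCR duplicates cannot be recognised from these counts.

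Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, and log2 CPM were computed with a prior count of 2, which understates the range of low genes. The edgeR filter (at least 10 counts at the median library size, at least 15 in total) was run without groups. It then requires a gene to reach the minimum in every library, so genes that are near 0 in some libraries were left out of the tests and are covered by the alternatives. It kept 12813 genes that hold 99.9% of all counts. For each of these a chi-square test of dispersion asked whether the 9 counts varied by more than counting noise, with Benjamini-Hochberg adjustment. A gene is called variable here when the adjusted p was under 0.05 and its highest and lowest library differed by at least 1 on the log2 scale, that is 2-fold. With no groups there was no coefficient that a quasi-likelihood test could test. The chi-square test does not separate biological variation from variation in sorting or library preparation.

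Before the data were examined, 25 gene lists, 26 genes to be named in any case, the tests and most of the alternatives were fixed. For each list with at least 3 measured members, the median range of its members was set against 10000 random lists matched on mean expression in 20 bins, and so was Kendall's W, which is 1 when every member ranks the 9 libraries alike. These percentiles describe these libraries. Genes are not independent replicates. The interval of a score range comes from 2000 bootstrap draws over list members. A list's score in a library is the median over its members of log2 CPM minus the gene's own median over the libraries. Genes named are those 26, the 2 measured members of widest range of each list, and the 10 genes of widest range among those with a mean of at least 5 CPM, leaving out predicted genes. Genes of lists that do not stand apart from random lists could be left out. Of the genes this rule takes, 2 are not reported here. Other genes in the text were chosen after their values were seen. They are Cdt1, some single markers of other cell types from the lists, and the neighbours of Aspn, Omd and Ogn.

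Of the listed symbols, 16 were found under a newer symbol through the RefSeq synonyms. Where a symbol stood on more than one row, the row with the higher total was used (Ddit3, whose other row holds 0 counts, and Aldoa, whose other row holds 84). Coordinates are those of GENCODE mouse release M21 on GRCm38, the same build. It has 55141 of the table's gene IDs and lacks 351.

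A correlation between list scores was planned only if the scores did not fall into separate clusters, judged by whether the mean silhouette of a 1-dimensional clustering exceeded the 95th percentile of 10000 simulated normal samples. The rule looked at single scores and would have allowed 17 lists to be correlated with the G2/M and mitosis score. By the same criterion, applied to the whole profile only after the data had been seen, the first principal component of all tested genes split the libraries into sets of 3 and 6 (silhouette 0.926 against 0.788) and the second into sets of 3, 3 and 3 (0.792 against 0.788, a narrow margin). Within the set of 6 (libraries 1, 3, 4, 6, 7 and 9), where the limit is 0.815, the results were mixed. The second component of all 9 libraries fell into clusters of 2, 2 and 2 (0.892) and the second component computed on the 6 alone into 3 and 3 (0.847), while the first component computed on the 6 alone (0.796) and the G2/M and mitosis score (0.695) did not pass the limit. Since part of the profile was clustered in that set too, no correlation between scores is given, a choice made after the data had been seen.

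The 36 pairs of libraries were checked for a library deposited more than once. The lowest chi-square per degree of freedom was 16.7, far above sampling noise, so all 9 were kept. The dispersion test was tested on simulated data drawn from the real means and library sizes, with 200 of 12813 genes changed in 3 of the 9 libraries. With counting noise only, 1 of 50 genes changed 1.5-fold, and 50 of 50 at each of 2.5-fold, 4-fold and 8-fold, were called, with 2 of 12613 unchanged genes called. A simulated random spread between libraries with a coefficient of variation of 10% gave 169 calls among the unchanged genes and one of 20% gave 4014. A planted list stood above all random lists in both measures, and of 200 random lists 14 exceeded the 95th percentile in spread and 7 in concordance. Alternatives were RLE size factors, library totals alone, no filter, a mean of at least 1 CPM, a prior count of 0.5, other definitions of the range, and each library left out in turn. Calculations outside R used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.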

Results

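The transcriptome of D2.0R cells was profiled after a week in medium with 2% serum, a setting in which cells that keep the CellTrace Far Red dye are the quiescent ones and cells that lose it the proliferating ones. The series asks how quiescent and proliferating cells of this line differ, in a study of natural killer (NK) cells and dormant breast cancer. The labels name 3 kinds of sample, CTFR-positive, CTFR-negative and bulk, but do not tie any library to a kind. The 9 libraries are therefore described one by one under their title numbers, and none is read as quiescent or proliferating. Library totals were 29058388 estimated counts in library 1, 34165502 in library 2, 35406270 in library 3, 31084648 in library 4, 27880290 in library 5, 33174708 in library 6, 41243036 in library 7, 35222378 in library 8 and 18732737 in library 9. Between 13095 genes (library 9) and 14390 genes (library 2) had at least 10 counts.

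The widest differences between libraries lay in genes of cell division. All 30 measured genes of the G2/M and mitosis list were variable, each was highest in library 8, and 19 of the 30 were lowest in library 3. Mki67, the gene of the proliferation marker Ki-67, stood at 5.64 CPM in library 1, 62.9 in library 2, 4.98 in library 3, 9.79 in library 4, 106 in library 5, 9.20 in library 6, 28.1 in library 7, 149 in library 8 and 24.1 in library 9. Its highest and lowest libraries differed 30.01-fold (95% interval 25.8 to 35.1). Top2a, a topoisomerase of dividing cells, ran from 10.0 CPM in library 3 to 132 in library 8, and Ccnb1, the mitotic cyclin B1, from 1.98 to 21.7 CPM in the same libraries. The members of widest range were Ccnb2, another mitotic cyclin, at 0.481 CPM in library 3 and 26.0 in library 8, and Hmmr, a spindle protein gene, at 0.623 and 27.5 CPM. The kinetochore genes Nuf2 and Cenpf, which were among the 10 genes of widest range, reached 16.1 and 43.5 CPM in library 8 against lowest values of 0.340 CPM in library 3 and 1.15 CPM in library 1. The members' median range was 3.77 on the log2 scale against 0.87 for random lists of like expression, above all 10000 of them. The members ranked the libraries almost alike (Kendall's W 0.964, again above all random lists). The list score was -1.52 in library 1, 0.85 in library 2, -1.68 in library 3, -0.81 in library 4, 1.65 in library 5, -1.33 in library 6, 0.28 in library 7, 2.13 in library 8 and 0 in library 9. Its range of 3.81 on the log2 scale (bootstrap interval over members 3.41 to 4.16) was 3.25 without library 8.

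Of these genes, Mki67 (ENSMUSG00000031004) lies on chromosome 7 at 135689784 to 135716361, Top2a (ENSMUSG00000020914) on chromosome 11 at 98992943 to 99024189, Ccnb1 (ENSMUSG00000041431) on chromosome 13 at 100778650 to 100786570, Ccnb2 on chromosome 9 at 70407692 to 70421547 and Hmmr on chromosome 11 at 40701395 to 40733422 of GRCm38. All are protein-coding, and a gene's value sums over its exons.

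**Figure D1:**
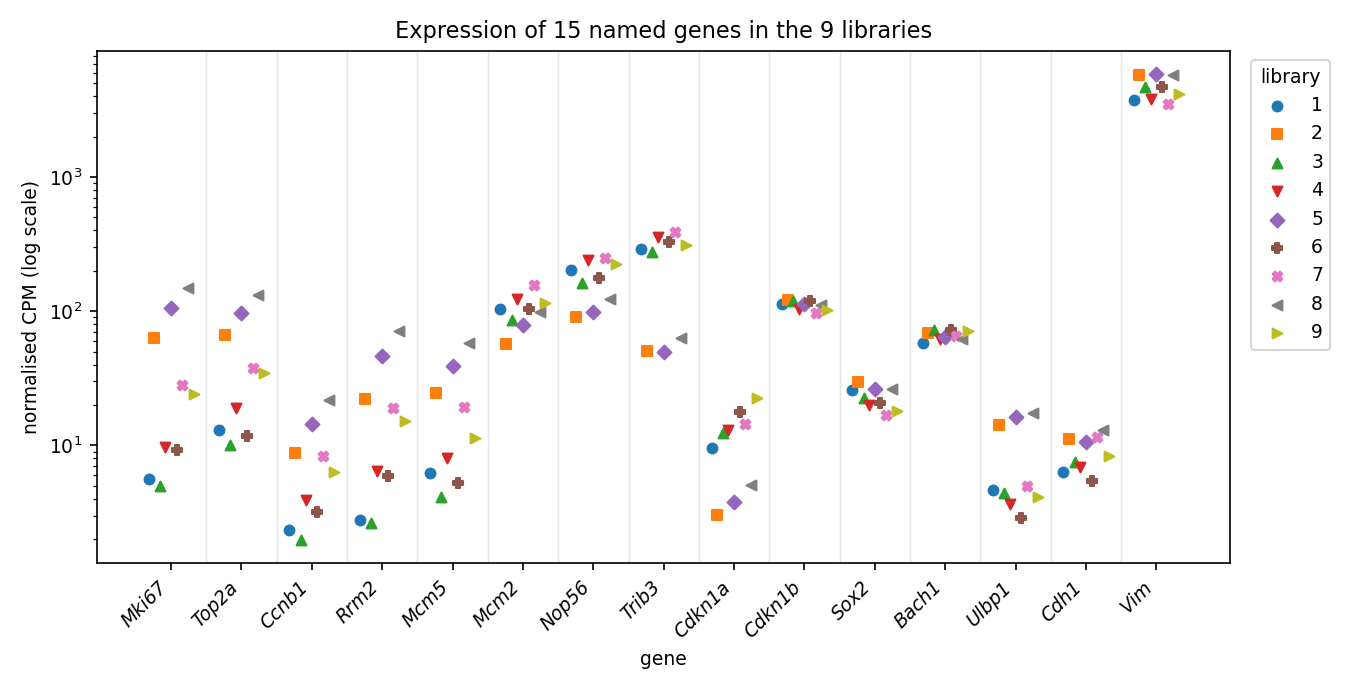
Normalised CPM (log axis) of 15 named genes, one symbol per library, with no error bars because each point is a single library. Mki67, Top2a, Ccnb1, Rrm2 and Mcm5 were highest in library 8 and lowest in library 3, while Cdkn1b and Bach1 differed between libraries by 1.25-fold each and Cdkn1a was lowest in library 2.

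Genes of DNA replication and S phase differed between libraries as well, but not all in the same order. Of 31 measured members 25 were variable, 26 were highest in library 8, and Kendall's W was 0.597, above all random lists. Rrm2, a subunit of ribonucleotide reductase, ran from 2.63 CPM in library 3 to 71.1 in library 8, and Mcm5, a subunit of the replicative helicase, from 4.16 to 57.5 CPM in the same libraries. Mcm2, another subunit of that helicase, had its lowest value, 57.3 CPM, in library 2 and its highest, 158 CPM, in library 7, and its range fell just under 2-fold (0.996 on the log2 scale) without library 2. Cdt1, a replication licensing factor named after its values were seen, was likewise lowest in library 2 (18.6 CPM) and highest in library 7 (68.4 CPM). Pcna, the sliding clamp of replication, varied beyond counting noise (chi-square test, adjusted p 7.95e-121) but only 1.71-fold, from 49.0 to 83.8 CPM. The list's score range moved from 1.38 to 1.11 on the log2 scale without library 8.

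Genes of cell cycle arrest shared an order over the libraries less than the division genes did, though more than random lists. Of 27 measured members of the arrest and quiescence list 13 were variable, with a W of 0.169 (percentile 99.2). The list score was highest in library 2 (0.31), where 10 members were highest, and lowest in library 7 (-0.26). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, stood at 9.51 CPM in library 1, 3.01 in library 2, 12.5 in library 3, 13.0 in library 4, 3.78 in library 5, 17.7 in library 6, 14.3 in library 7, 5.06 in library 8 and 22.6 in library 9, a 7.50-fold range (95% interval 6.04 to 9.37). Cdkn1a was thus lowest in library 2, where the list score was highest. Cdkn1b, which encodes the inhibitor p27, ranged only from 96.4 to 120 CPM, and Ccng2, a cyclin of non-dividing cells, from 79.5 to 121 CPM. Cdkn1c, the gene of the inhibitor p57, had 0 counts in all libraries. The floor of 3 counts corresponds to 0.0742 CPM in library 7, the deepest, and to 0.164 CPM in library 9, the shallowest. Gadd45b, a stress response gene, had a range from 5.31 CPM in library 9 to 30.1 in library 2. Among 19 measured p53 targets 9 were variable, including Gdf15, a stress-induced cytokine gene, at 2.25 CPM in library 2 and 11.35 in library 7. Their spread lay above 99.2% of random lists, whereas their concordance (W 0.121, percentile 93.3) did not stand apart, except without library 6 or library 9 (percentiles 95.1 and 95.6).

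Of the 23 genes linked to stem cells, 6 stayed under 1 CPM in every library and 17 could be measured. Of these, 6 were variable, and their order over the libraries was no more alike than in random lists (W 0.031, percentile 24.7). The spread of the list (percentile 99.6) fell to 92.6 without library 7. Sox2, a pluripotency transcription factor gene, ranged 1.75-fold, from 16.9 CPM in library 7 to 29.5 in library 2, and Bach1, a haem-regulated transcription factor gene, 1.25-fold, from 58.2 to 72.9 CPM. Cd44 ranged from 276 to 491 CPM and Ly6a, the gene of Sca-1, from 43.3 to 84.4 CPM, both under 2-fold, although with libraries scaled by totals alone Ly6a passed it (1.02 on the log2 scale). Itga6, the integrin alpha 6 gene, ranged from 10.1 to 22.1 CPM. The members of widest range were Klf4, at 9.64 CPM in library 2 and 50.5 in library 7, and Abcg2, an efflux pump gene, which ranged from 56.0 CPM in library 8 to 274 in library 9.

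Of 22 mesenchymal and matrix genes 3 stayed under 1 CPM in every library. Vim, the vimentin gene, lay between 3495 CPM in library 7 and 5849 in library 5. Of 19 epithelial genes 12 stayed under 1 CPM in every library. Epcam, which encodes an epithelial adhesion molecule, reached at most 0.219 CPM, and Cdh1, the E-cadherin gene, ran from 5.46 CPM in library 6 to 13.0 in library 8. The keratin genes Krt8 and Krt18 were expressed, Krt8 from 146 CPM in library 3 to 662 in library 8 and Krt18 from 38.0 CPM in library 9 to 156 in library 1. The 6 measured epithelial genes, of which 5 were variable, had a W of 0.434 (percentile 97.49, and 94.7 without library 9). Of 19 measured mesenchymal and matrix genes 12 were variable and their W was 0.394, above all random lists. Thbs1, the thrombospondin 1 gene, ranged from 191 CPM in library 9 to 1617 in library 5, and Zeb1, a repressor of epithelial genes, ran from 0.328 CPM in library 9 to 3.90 in library 1. In the list of TGF-beta and BMP response genes 8 of 12 were variable (W 0.308, percentile 98.8), among them Ccn2, a matricellular protein gene, at 9.63 CPM in library 9 and 176 in library 2, and Id3, a BMP target, at 10.2 CPM in library 7 and 77.6 in library 2.

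The interferon response list had 11 variable genes of 28 measured and a W of 0.494, above all random lists. Its score was 0.48, 0.40 and 0.43 in libraries 2, 5 and 8 and 0 or below in the others. The highest score, in library 2, and the lowest, in library 9 (-0.20), differed 1.59-fold. Mx1, an antiviral gene, ranged from 7.27 to 25.8 CPM, Gbp2 from 18.0 to 77.2 CPM and Isg15 only from 128 to 209 CPM. In the MHC class I antigen presentation list 6 of 16 genes were variable, with a W of 0.235 (percentile 95.1). That percentile fell below 95 without library 1, 2, 4 or 7, to 85.8 without library 2, and to 94.3 without a filter and 94.4 with a mean of at least 1 CPM, and the percentile of its spread (97.4) fell to 94.1 without library 8. B2m, the light chain of MHC class I, ranged from 892 CPM in library 8 to 1563 in library 3, and H2-K1 from 206 to 326 CPM. The proteasome subunit gene Psmb9 ran from 4.92 CPM in library 9 to 22.1 in library 5, and the peptide transporter gene Tap2 from 62.5 to 179 CPM in libraries 9 and 2.

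Among ligands of NK cell receptors, 9 of 14 listed genes could be measured and 5 of these were variable, in no more alike an order than in random lists (W 0.033, percentile 8.21). The spread of this list (percentile 99.4) fell to 93.6 without a filter on low counts. Ulbp1 (ENSMUSG00000079685, chromosome 10 at 7440362 to 7473638), a ligand of the activating receptor NKG2D, stood at 4.67 CPM in library 1, 14.3 in library 2, 4.41 in library 3, 3.66 in library 4, 16.4 in library 5, 2.85 in library 6, 5.02 in library 7, 17.4 in library 8 and 4.16 in library 9. That was a 6.08-fold range (95% interval 4.89 to 7.65). Raet1e, another NKG2D ligand gene from a family of similar copies, reached at most 0.139 CPM. Fas, a death receptor gene that the list also holds, ranged from 4.401 to 17.8 CPM. Of 28 markers of NK cells, leukocytes and endothelium, none exceeded 11.98 CPM, and each of these 3 lists had only 2 measured members. Single markers of other cell types outside the rule for named genes, here and among the fibroblast genes, were chosen after their values were seen. Ncr1, Klrk1, Klrd1, Gzma, Nkg7 and Cdh5 had 0 counts in all libraries, and Ptprc, the pan-leukocyte gene CD45, reached at most 0.109 CPM. The markers that passed 1 CPM were Cd68 and Cd14, at 2.74 to 10.95 and 2.13 to 7.24 CPM, Egfl7 at 6.79 to 11.98 CPM, and Eomes, Klrb1c, Vwf and Il2rb, whose highest values were 3.28, 2.94, 4.25 and 1.70 CPM. Of the fibroblast genes Pdgfra, Pdgfrb, Col1a1 and Col3a1 were abundant and variable, with Col3a1 between 394 CPM in library 9 and 2984 in library 2, whereas Dcn, Lum, Dpt, Pdpn and Thy1 stayed below 1 CPM. The 4 measured fibroblast genes had a spread above 99.99% of random lists and a W of 0.675 (percentile 94.6), which passed 95 in several settings, such as 95.5 with RLE size factors and 97.1 with totals alone.

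Genes of stress responses and of growth differed between libraries as well. In the unfolded protein and amino acid response list 12 of 15 genes were variable and W was 0.432 (percentile 99.8). Trib3, a target of ATF4, stood at 292 CPM in library 1, 50.8 in library 2, 277 in library 3, 358 in library 4, 49.3 in library 5, 327 in library 6, 388 in library 7, 62.9 in library 8 and 312 in library 9. Ddit3, which encodes CHOP, ranged from 52.8 CPM in library 5 to 287 in library 7. Atf3 ranged from 2.82 to 19.5 CPM. Of 14 oxidative stress genes 6 were variable, with a spread above 99.8% of random lists and a W that did not stand apart (0.216, percentile 91.1, and 95.7 with totals alone). Slc7a11, the cystine transporter gene, ranged from 79.1 CPM in library 5 to 632 in library 1, and Hmox1, the haem oxygenase 1 gene, from 165 CPM in library 8 to 579 in library 1. Ribosome biogenesis genes moved closely together, with 15 of 20 variable, 19 of 20 lowest in library 2, 16 highest in library 7 and a W of 0.941, above all random lists. Nop56, a nucleolar protein gene, ranged from 90.0 to 248 CPM and Rrp12, a ribosome assembly gene, from 20.2 to 57.0 CPM in libraries 2 and 7.

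In cholesterol synthesis 11 of 19 genes were variable and 18 of the 19 were lowest in library 1 (W 0.652, above all random lists), with Idi1 at 38.9 CPM in library 1 and 138 in library 8 and Nsdhl at 26.3 and 103 CPM. In glycolysis and hypoxia 13 of 17 were variable (W 0.561, above all random lists). Of the 17, 12 were highest in library 7 and 9 lowest in library 3. Car9 went with these, at 0.849 CPM in library 3 and 3.54 in library 7. Adm, a hypoxia-induced peptide gene, did not, at 1.04 CPM in library 9 and 12.1 in library 1. Of 20 lysosome and autophagy genes 7 were variable, and 17 of the 20 were lowest in library 8 (W 0.604, above all random lists). Their spread (percentile 99.4) rested on that library and fell to a percentile of 55.8 without it, and to 76.4 by the interquartile range. Of these, Sqstm1, the autophagy receptor p62, ranged from 840 to 1984 CPM and Neu1 from 49.5 to 111 CPM, a range that fell under 2-fold (0.80 on the log2 scale) without library 8. Inflammatory cytokine and protease genes had 12 variable members of 14 (W 0.224, percentile 98.95, and 93.6 without library 3), with Mmp3 at 17.4 CPM in library 7 and 188 in library 1 and Mmp13 between 1.38 and 12.3 CPM. Immediate early genes had 11 of 18 (W 0.206, percentile 98.0, and 94.7 without library 7), with Zfp36 between 49.7 and 207 CPM.

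As signs of library quality, the mitochondrially encoded genes held 1.21% of the counts in library 3 to 1.93% in library 4, and the 10 most abundant genes 5.08% in library 8 to 6.09% in library 1. The spread of the 13 mitochondrial genes did not stand apart (percentile 91.4), except without library 2, 7 or 8 (97.3, 96.0 and 95.2) and by the interquartile range (97.7), but they ranked the libraries alike (W 0.813), 9 of them lowest in library 8. Within this list mt-Nd1 ranged from 777 to 1972 CPM and mt-Nd3 from 5.39 to 19.9 CPM, the latter with a range of 0.95 on the log2 scale without library 8. Only 4 of 15 replication-dependent histone genes, most of whose transcripts lack the poly(A) tail that was selected for, could be measured. Their score was lowest in library 8 and highest in library 3, and their spread did not stand apart (percentile 86.25), while their W of 0.671 did (percentile 98.6).

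**Figure D2:**
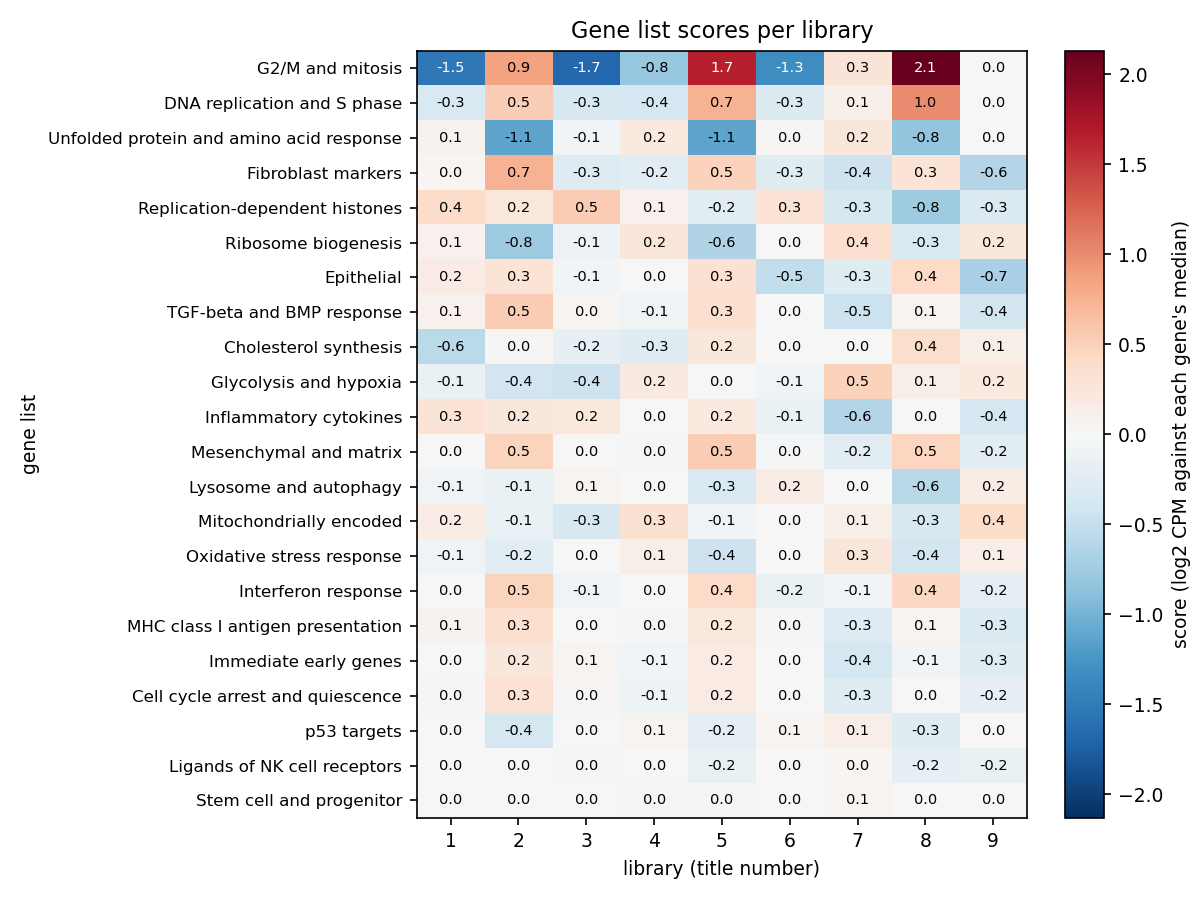
Scores of the 22 tested gene lists (rows, ordered by score range) in the 9 libraries (columns, title numbers), as the median over members of log2 CPM minus the gene's own median. The G2/M and mitosis score ran from -1.68 in library 3 to 2.13 in library 8.

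Over all genes, 12059 of 12813 tested (94.1%) varied between libraries by more than counting noise (chi-square test, Benjamini-Hochberg adjusted), and 3592 of them (28.0% of those tested) were variable with a range of at least 2-fold. The median gene had a range of 0.69 on the log2 scale, or 1.61-fold, against 0.14 in simulated libraries with counting noise only. Those libraries held 0 variable genes, which the test nearly ensures, since it allows for just such noise. In them 180 genes reached a range of at least 2-fold by counting noise. Of the 22 lists with enough members, 20 lay above the 95th percentile in spread and 17 in concordance, where chance would give 1.1. Adjusted over the list alone, the count of variable members was the same in each of the 25 lists. By the silhouette criterion, 4 list scores fell into separate clusters. Libraries 2, 5 and 8 formed the high cluster for interferon response and for mesenchymal and matrix genes (0.48, 0.54 and 0.46 in the latter). They formed the low cluster for the unfolded protein and amino acid response (-1.13, -1.12 and -0.84). These libraries also had the highest G2/M and mitosis scores. For ligands of NK cell receptors, libraries 5, 8 and 9 were apart instead. The count of variable genes has no replicate error behind it. A random spread with a coefficient of variation of 20% between otherwise equal libraries gave 4014 calls among 12613 simulated unchanged genes.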

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

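The count of 3592 variable genes stayed within 1.5 times under RLE size factors, total scaling, a mean of at least 1 CPM, a prior count of 0.5 and a thinning of every library to the smallest total (chosen after seeing the data), between 3365 and 3646, and between 3268 and 3560 with each library left out in turn. Without a filter it rose to 6374, because more genes were tested. It was 740 with a range of at least 2 on the log2 scale and 1894 when the second highest library was set against the second lowest, both stricter by construction. The number of lists above the 95th percentile stayed between 19 and 21 in spread and between 16 and 19 in concordance under RLE size factors, total scaling, either other filter, a prior count of 0.5 and, for the spread, the interquartile range, and with each library left out. For single lists, the concordance percentile fell below 95 in 2 such settings and 7 left-out libraries and rose above it in 4 and 7, and the spread percentile fell below it in 2 and 3 and rose above it in 1 and 3. The range of the G2/M and mitosis score, 3.81 on the log2 scale, was between 3.25 (without library 8, which holds the highest score) and 3.82 with one library left out. The share of variance on the first principal component, 53.6%, was 30.5% without a filter, which adds genes with few counts, 58.4% in the 500 genes of widest range, and between 46.9% (without library 5) and 58.9% (without library 1) with one library left out. No paired analysis was possible because no library has a group. A check of correlations without the 2 farthest libraries was laid down but not run, since no correlation is given. Low depth limits the genes below about 1 CPM, and library 9, with the fewest counts, most of all.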

Other observations

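All tests in this part were chosen after the data had been seen. Apart from the division genes, the genes of widest range among those above 5 CPM included 3 members of the small leucine-rich proteoglycan family of matrix genes. Ogn, which encodes osteoglycin, stood at 119 CPM in library 1, 307 in library 2, 61.5 in library 3, 70.2 in library 4, 188 in library 5, 26.9 in library 6, 21.9 in library 7, 91.9 in library 8 and 8.42 in library 9. Omd, the osteomodulin gene, ranged from 1.20 CPM in library 9 to 69.6 in library 2, and Aspn, the asporin gene, from 0.109 to 43.8 CPM in the same libraries, the lower value resting on 2 counts. Hepacam2 stood at 0.209, 0.796 and 1.25 CPM in libraries 1, 2 and 3, at 2.24, 3.60 and 5.49 CPM in libraries 4, 5 and 6, and at 9.10, 15.8 and 19.1 CPM in libraries 7, 8 and 9. Rn7s1, a copy of the multicopy 7SL RNA, had 0 counts in libraries 1, 8 and 9 and up to 13.3 CPM in library 5, and its reads cannot be assigned to 1 copy with certainty. Aspn, Hepacam2 and Rn7s1 did not pass the count filter and so had no dispersion test in the main result.

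The 9 libraries fell into separate sets over all tested genes. On the first principal component, with 53.6% of the variance, the values were 0.13 in library 1, -0.36 in library 2, 0.14 in library 3, 0.20 in library 4, -0.38 in library 5, 0.19 in library 6, 0.21 in library 7, -0.35 in library 8 and 0.23 in library 9. On the second, with 25.8%, they were 0.26, 0.15 and 0.21 in libraries 1, 2 and 3, 0.04, -0.01 and 0.03 in libraries 4, 5 and 6, and -0.24, -0.22 and -0.23 in libraries 7, 8 and 9. Laid out by title number in 3 rows of 3, differences between the rows (1 to 3, 4 to 6, 7 to 9) held 27.8% of the variance and differences between the columns (1, 4 and 7, then 2, 5 and 8, then 3, 6 and 9) held 61.8%. The idea that title numbers are unrelated to the profiles was tested against all 5040 ways of laying 9 libraries out in 3 rows and 3 columns. Only 1, the layout by title number, reached its 89.6%, and the highest other layout had 86.6%. The median layout held 50%, so a large share arises from any layout. The title numbers may therefore follow a crossed scheme of 2 factors with 3 levels each, for example kind of sample and day or flask. The labels do not say which of the factors, if either, is the kind of sample. The G2/M and mitosis score was highest in the middle library of each row, at 0.85 in library 2, 1.65 in library 5 and 2.13 in library 8. It also rose down each column, for example from -1.52 in library 1 to 0.28 in library 7. Division genes thus differed along both factors, and these values do not tell a batch from a biological factor. No biological explanation was tested.

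The wide range of the G2/M and mitosis score was set against 3 technical explanations. A difference in library depth would have it shrink when every library is thinned to the smallest total, and it was 3.82 on the log2 scale after thinning against 3.81 before. A factor common to a library moves all its genes alike, so it cancels when the members' median deviation from their mean is taken relative to that of all tested genes in the same library, and the range of this difference was 3.824. RNA from leukocytes, NK cells or endothelium would bring their abundant transcripts, and the highest of 28 markers in any library was Egfl7 at 11.98 CPM. The tables argue against all 3 as the cause. A real difference in the share of dividing cells stays open and was not tested, since the libraries have no group.

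Aspn, Omd and Ogn lie side by side on chromosome 13, at 49544443 to 49567565, 49582462 to 49592822 and 49608046 to 49624501 of GRCm38. A change across the whole chromosomal region, such as a gain or loss in some cells, was tested on the 8 genes within 500 kb that passed the count filter, leaving out Omd and Ogn. Their median range was 0.643 on the log2 scale, close to the 0.69 of all tested genes, and 2 of the 8 exceeded 1, Fgd3 at 1.98 and Iars, with values from 146 CPM in library 5 to 359 in library 1. Fgd3 was, like Aspn, Omd and Ogn, highest in library 2 and lowest in library 9. Ecm2, next to Aspn, was left out by the count filter, as Aspn was, but its range was 3.61, from 0.0495 CPM in library 7 to 1.31 in library 2. The lower value lies below the floor of 3 counts, 0.0742 CPM in library 7, so the size of this range is uncertain. The ranges of Ogn and Omd were 5.18 and 5.78, so these values argue against a change of like size across the whole region. A regional change of lesser size cannot be judged, since it could lie within the 0.69 of the median gene. A change of a smaller segment that includes Ecm2, regulation of these genes, and a difference in the cells that express them stay open and untested.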
